A study of Mus musculus with 6 samples.

How the data were processed

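RNA sequencing libraries of Lewis cells, a mouse lung carcinoma line, were compared. There were 3 libraries from cells kept for 72 h in medium with 2% fetal bovine serum (FBS) and 3 from cells kept for the same time in 10% FBS. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with an NEBNext Ultra RNA kit. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Whether messages were selected by their poly(A) tails is not given in the sources used here.

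Per the submitters' processing notes, the tools were FastQC 0.11.5, HISAT2 2.1.0, StringTie 1.3.3b and DESeq 1.28.0, with the mouse build mm10. The notes give no order or settings. The deposited files hold 1 expression value per gene and library, taken here as FPKM from the values themselves, since no label names the unit. The sums over genes differed between libraries (320918 to 339694), and low values multiplied by exon length lay near whole multiples of a common step more often than by chance. Each of the 33007 genes carries an identifier, a symbol and a position. The authors' deposited table also gives a log2 fold change and a p-value per gene for the comparison of the 2 groups, with a p-value for 14642 genes. How these were made, and whether the p-values are adjusted, is not given in the sources used here, and they were used only for a comparison of calls. The files hold 3 further columns of per-sample values that match no sample of the series, and these were not used.

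Because the values are FPKM and not counts, the branch of the design for normalized values applied. Genes were kept where at least 3 of the 6 libraries reached 1 FPKM, which left 12591 genes. Values were transformed as log2(FPKM + 1) and fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend, 4 residual degrees of freedom) with the serum group as the only term. Adjusted p is Benjamini-Hochberg over all tested genes, with a threshold of 0.05. A log2 fold change is that of FPKM + 1, 2% over 10% FBS, so it understates the change of genes at low values. No scaling between libraries was added. The median log2 fold change of all tested genes was 0.12, and median-of-ratios scaling moved it by -0.12, so list medians in the results are given relative to the median of all tested genes unless stated. Medians under the alternatives and in the closing section are not.

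There were 26 gene lists, fixed with the tests and most alternatives before the data were examined. A list was tested with camera (limma) when at least 5 members had been tested, which held for 23 lists, with a preset correlation of 0.01 between genes, two-sided, and Benjamini-Hochberg adjustment over the lists. The others had 2 to 4 tested members. The test was repeated with the correlation estimated per list. Counts of members that rose or fell use the adjustment over all genes. The count adjusted over the list alone was the same where none is given.

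Genes named with full values followed a fixed rule. It took the 5 largest and the 5 lowest log2 fold changes among genes past the threshold with a mean of at least 5 FPKM in the higher group and no overlap between groups, passing over genes without a symbol, Gm and Rik models and symbols ending in -ps. It added the 2 members with the lowest adjusted p from each list that passed and 1 from each other list, ties by the larger fold change, and always Mki67, Ccnd1, Myc, Cd274, Vegfa and 2 genes that are not reported here. This gave 49 genes. For a symbol on several rows (63 symbols) the row with the highest sum carried the symbol.

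FPKM keeps no read counts. If the commonest step of each library is 1 fragment, the libraries held 16580000 to 17940000 fragments. Of low values, 44.7% to 47.0% lay within 0.1 of a whole fragment, against 20% by chance, so whole reads were not recovered and a count model was not run. On data simulated from the real means with 200 changed genes among 11261 tested, the fit recovered 14% of 50 genes changed 1.2-fold, 82% of 50 changed 1.5-fold, 92% of 50 changed 2-fold and 94% of 50 changed 4-fold. Of its calls on these data 6.4% were false, and it called 0 genes where nothing had been changed. The means were those of the 10% FBS libraries, 25 further genes were raised as a list, and none was raised from 0. Every gene was given the same dispersion (spread beyond sampling), 0.0025, taken from abundant genes in the 10% FBS libraries. The simulated spread of other genes may therefore be too small. In the real data 64.5% of tested genes were called, a far larger share than was changed in the simulation, so these rates may not carry over.

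Gene positions are those of the deposited files. GENCODE M21, an annotation of the same assembly, held 32948 of the identifiers, and 95.9% of all genes had the same chromosome, strand, start and end there. It supplied exon lengths, GC content and transcripts. The transcripts of the named genes and of the members of the interferon and hypoxia lists were searched with BLAST+ 2.17.0 for other genes with at least 95% identity over at least 50% of the longest transcript, and their exons for overlap with other genes. The kit named in the labels does not mark strand, so reads of overlapping genes on opposite strands cannot be told apart.

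Alternatives were a pseudocount of 0.1, no filter, a filter at 5 FPKM, median-of-ratios scaling, quantile normalization, the 20 most abundant genes left out, the replicate number as a block, each library left out in turn, and for lists the estimated correlation and the rotation test fry. Added after the data were seen were limma-voom on fragments estimated from FPKM and exon length, and removal of trends with GC content and exon length.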

Results

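Gene expression was measured in Lewis cells, a mouse lung carcinoma line, after 72 h in medium with 2% or 10% fetal bovine serum (FBS), which supplies growth factors, lipids and hormones. Each group had 3 libraries. The FPKM values of a library summed to 323030 ± 2138 in 2% FBS and 337920 ± 1746 in 10% FBS (SD, n = 3). On average 12615 ± 14.1 genes reached 1 FPKM in 2% FBS and 11898 ± 39.6 in 10% FBS (SD, n = 3). Transcripts of the mitochondrial genome took 6.98% ± 0.212 of the FPKM sum in 2% FBS and 8.47% ± 0.199 in 10% FBS (SD, n = 3). Across the 12591 tested genes, which are not independent replicates, the correlation of log values was 0.988 to 0.992 within groups and 0.932 to 0.935 between them.

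The comparison of low with normal serum asked which genes differ between these culture conditions. In 2% FBS all 31 tested interferon response genes rose, as did 20 of 25 chemokines, cytokines and NF-kB targets. So did 18 of 21 antigen presentation genes and 23 of 24 genes in the list of the stress factor ATF4. Of genes of glycolysis and hypoxia 25 of 27 fell, as did all 25 genes of mitosis and 21 of 25 of sterol synthesis and uptake. These lists and 5 others passed camera with the preset correlation, but none of the 12 passed with the correlation estimated per list, where the lowest adjusted p was 0.0503. Among the genes named by rule, the largest rise in log2(FPKM + 1) was in Isg15, a ubiquitin-like protein induced by interferon, from 2.15 ± 0.589 FPKM in 10% FBS to 158 ± 26.0 in 2% FBS (SD, n = 3). The largest fall on that scale was in Selenbp1, a selenium-binding protein, from 53.7 ± 5.68 to 5.03 ± 0.575 FPKM (SD, n = 3). In all, 5319 genes were higher and 2807 lower in 2% FBS (limma, adjusted p under 0.05), and 608 and 265 of these changed at least 2-fold. The count at least 2-fold higher was 1059 with a pseudocount of 0.1, 1073 with limma-voom and 397 with the filter at 5 FPKM. The groups did not overlap for 70.4% of the tested genes, where chance gives 10%. The split between higher and lower calls depended on scaling. It was 4020 higher and 3980 lower with median-of-ratios scaling, and 3752 and 3914 with quantile normalization. In the authors' deposited table, 997 genes were at least 2-fold higher and 932 at least 2-fold lower with a p-value under 0.05. Of those in the authors' deposited table, 711 and 669 were tested here, and 710 were called higher and 616 lower at any fold size. Those also called at least 2-fold changed here numbered 563 higher and 260 lower.

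The other genes with the largest rises on that scale were Cxcl10, Ccl20, Ifi44 and Rsad2. With a pseudocount of 0.1 the order changed, with 7.85 for Ifi44, 7.60 for Rsad2, 6.26 for Cxcl10 and 6.16 for Isg15. Isg15 (ENSMUSG00000035692, mm10 chromosome 4, 156199424 to 156200818, minus strand) had a log2 fold change of 5.66 ± 0.17 (SE, limma adjusted p = 1.51e-06). Cxcl10 (ENSMUSG00000034855, chromosome 5, 92346638 to 92348889, minus strand), a chemokine induced by interferon, rose from 0.527 ± 0.0780 to 47.9 ± 5.6 FPKM (SD, n = 3). Its log2 fold change was 5.00 ± 0.09 (SE, limma adjusted p = 2.70e-07). Ccl20 (ENSMUSG00000026166, chromosome 1, 83116766 to 83119167, plus strand), a ligand of the receptor CCR6, rose from 0.607 ± 0.156 to 45.9 ± 3.92 FPKM (SD, n = 3). Ifi44 (ENSMUSG00000028037, chromosome 3, 151730922 to 151749960, minus strand) was listed at 0.0280, 0 and 0.0296 FPKM in the 10% FBS libraries and at 25.6, 27.7 and 28.6 in the 2% FBS libraries. Rsad2 (ENSMUSG00000020641, chromosome 12, 26442746 to 26456452, minus strand), which encodes the antiviral enzyme viperin, rose from 0.0480 ± 0.0332 to 28.1 ± 2.37 FPKM (SD, n = 3). The transcript of Isg15 has a near-identical copy in another gene model, so its level is uncertain.

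Among the largest falls, Bnip3 (ENSMUSG00000078566, chromosome 7, 138890836 to 138909519, minus strand), a mitophagy receptor induced by hypoxia, went from 175 ± 3.83 to 21.1 ± 0.351 FPKM (SD, n = 3). Its log2 fold change was -2.99 ± 0.03 (SE, limma adjusted p = 8.98e-08), and a gene model on the opposite strand shares 22.3% of its exons. Egln3 (ENSMUSG00000035105, chromosome 12, 54178981 to 54203860, minus strand), an oxygen-dependent prolyl hydroxylase, fell from 308 ± 9.0 to 39.3 ± 2.30 FPKM (SD, n = 3). S100a4 (ENSMUSG00000001020, chromosome 3, 90603771 to 90606045, plus strand), a calcium-binding protein linked to metastasis, fell from 415 ± 9.52 to 54.4 ± 9.06 FPKM (SD, n = 3). The gene model Gm42674 shares 51.7% of the exons of S100a4, and Selenbp1 (ENSMUSG00000068874, chromosome 3, 94933056 to 94944758, plus strand) has a near-identical copy, Selenbp2, so both levels are uncertain. Exosc6 (ENSMUSG00000109941, chromosome 8, 111056339 to 111057664, plus strand) was listed at 0.0227, 3.06 and 14.9 FPKM in 2% FBS and at 23.2, 39.7 and 26.8 in 10% FBS. All of its exons lie within those of Aars on the same strand, so reads of these genes cannot be assigned with certainty. The call on Exosc6 (log2 fold change -2.90, limma adjusted p = 0.0307) was lost with a pseudocount of 0.1 (adjusted p = 0.0695), without the filter (0.0727), without 2% FBS replicate 2 (0.0701) and without 10% FBS replicate 1, 2 or 3 (0.0615, 0.0867 and 0.0711). Without 2% FBS replicate 1 the log2 fold change of Exosc6 was -1.91, and over all alternatives its adjusted p ran from 0.00311 to 0.0867.

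**Figure D1:**
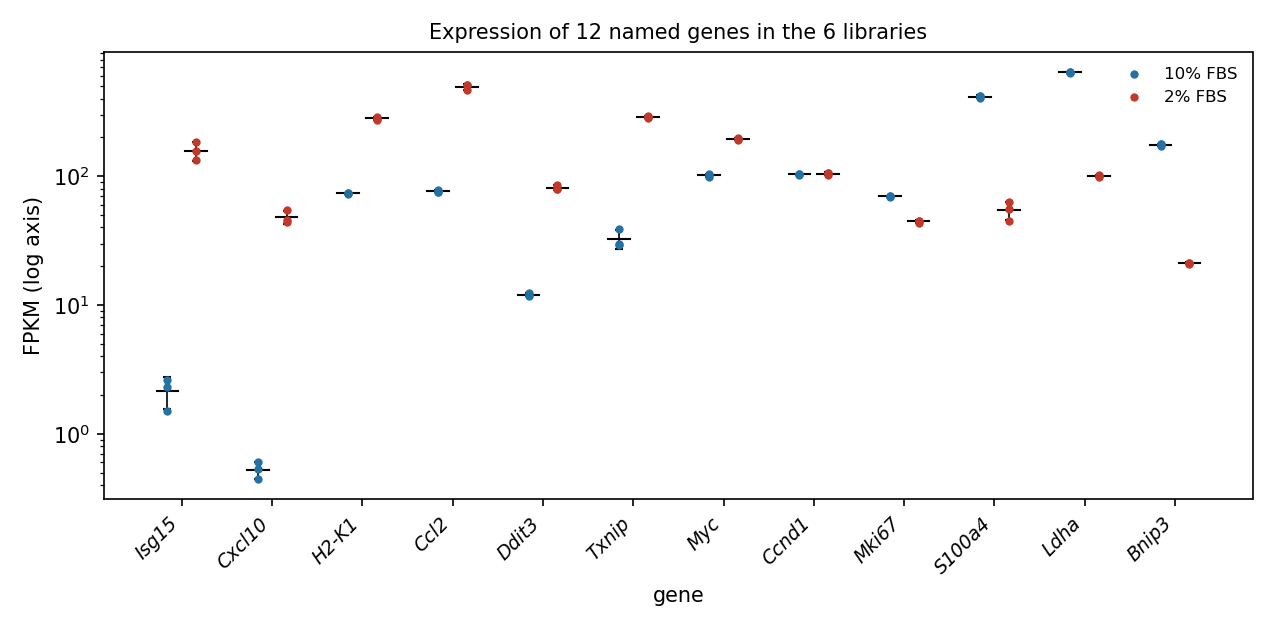
FPKM of 12 named genes in each library (points, log axis), with the mean (bar) and SD (whisker) of the 3 libraries of 10% FBS (blue) and of 2% FBS (red). The groups do not overlap for any gene shown except Ccnd1, with 104 ± 2.66 FPKM in 2% FBS and 103 ± 0.720 in 10% FBS.

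Immune genes rose together. All 31 tested members of the interferon response list rose in 2% FBS, among them the sensors Ddx58 and Ifih1, the transcription factors Stat2, Irf7 and Irf9, and the effectors Oas2, Mx2 and Bst2. Their median log2 change was 3.81 relative to all tested genes (camera adjusted p = 5.6e-15, and adjusted p = 0.164 with an estimated correlation). Not set against all genes it was 3.93, in a range of 3.29 to 6.20 over the alternatives, and 2.26 to 2.35 over the 11 members left when the filter was applied anew without a 2% FBS library. Of 21 tested genes of antigen presentation by major histocompatibility complex (MHC) class I, 18 rose, 1 fell (Pdia3, a chaperone) and 2 did not pass. Their median was 1.11 relative to all genes (camera adjusted p = 6.46e-06, and adjusted p = 0.0563 with an estimated correlation). The class I heavy chain gene H2-K1 rose from 73.5 ± 1.04 to 281 ± 8.43 FPKM and H2-Q4 from 14.9 ± 0.808 to 100.4 ± 3.48 (SD, n = 3). Cd274, which encodes the checkpoint ligand PD-L1, rose from 1.75 ± 0.0792 to 8.59 ± 0.415 FPKM (SD, n = 3), a log2 fold change of 1.80 ± 0.05 (SE, limma adjusted p = 1.41e-06). Of 25 tested chemokines, cytokines and NF-kB targets, 20 rose, 3 fell (Il33, Il11 and Lif) and 2 did not pass. Their median was 0.97 relative to all genes (camera adjusted p = 0.000133, and adjusted p = 0.0563 with an estimated correlation). Not set against all genes it was 1.09, in a range of 0.61 (no filter) to 2.17 (filter at 5 FPKM). Ccl2, which attracts monocytes, rose from 76.4 ± 1.57 to 495 ± 27.1 FPKM (SD, n = 3).

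Glycolysis and hypoxia genes moved the other way. Of 27 tested members, 25 fell and 2 did not pass, with a median of -1.86 relative to all genes (camera adjusted p = 1.4e-16, and adjusted p = 0.0563 with an estimated correlation). Ldha, the lactate dehydrogenase subunit at the end of glycolysis, fell from 641 ± 4.71 to 101 ± 1.71 FPKM (SD, n = 3), a log2 fold change of -2.65 ± 0.03 (SE, limma adjusted p = 8.98e-08). Genes along the pathway fell, among them Slc2a1, Hk1, Gpi1, Pfkl, Aldoa, Tpi1, Pgk1, Pgam1 and Eno1. Near-identical copies exist for Ldha (2 gene models), Pgk1 and Eno1, so their levels are uncertain. Vegfa, a growth factor of blood vessels induced by hypoxia, fell from 43.8 ± 0.814 to 38.6 ± 1.34 FPKM (SD, n = 3), a log2 fold change of -0.18 ± 0.04 (SE, limma adjusted p = 0.00459). Of 30 tested nuclear genes of oxidative phosphorylation, 26 fell (27 adjusted over the list alone), 0 rose and 4 did not pass. Their median was -0.44 relative to all genes (camera adjusted p = 3.13e-10, and adjusted p = 0.0563 with an estimated correlation). Atp5b, a catalytic subunit of ATP synthase, fell from 333 ± 1.12 to 207 ± 2.84 FPKM and Cox6b1, a subunit of cytochrome c oxidase, from 88.1 ± 1.07 to 54.8 ± 0.827 (SD, n = 3).

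Genes of sterol synthesis and uptake were lower in 2% FBS. Of 25 tested, 21 fell (22 adjusted over the list alone), 0 rose and 4 did not pass. Their median was -0.90 relative to all genes (camera adjusted p = 1.22e-11, and adjusted p = 0.0563 with an estimated correlation). Hmgcs1, an enzyme early in cholesterol synthesis, fell from 36.7 ± 0.826 to 14.4 ± 0.486 FPKM (SD, n = 3), a log2 fold change of -1.30 ± 0.04 (SE, limma adjusted p = 1.32e-06). Of 25 fatty acid synthesis genes 10 rose, 8 fell and 7 did not pass (12 and 9 adjusted over the list alone rose and fell, camera adjusted p = 0.634). Fads3, a member of the desaturase family, rose from 6.99 ± 0.286 to 17.8 ± 0.192 FPKM (SD, n = 3). Of 9 tested genes in the LXR and cholesterol efflux list 3 rose, 3 fell and 3 did not pass (camera adjusted p = 0.835). Myo1e fell from 26.8 ± 0.599 to 14.3 ± 0.143 FPKM (SD, n = 3). In the fatty acid oxidation and PPAR list 10 of 19 fell (11 adjusted over the list alone), 5 rose and 4 did not pass. Its median was -0.26 relative to all genes (camera adjusted p = 0.0409, and adjusted p = 0.164 with an estimated correlation). Cpt1a, which brings fatty acids into mitochondria, fell from 28.6 ± 1.18 to 10.9 ± 0.272 FPKM (SD, n = 3). Acot2, a mitochondrial thioesterase with the near-identical copy Acot1, rose from 4.82 ± 0.11 to 14.3 ± 0.447 FPKM (SD, n = 3). The call on the oxidation list was lost in 8 further alternatives, among them the filter at 5 FPKM (camera adjusted p = 0.0505), median-of-ratios scaling (0.0766) and quantile normalization (0.0627), in a range of 0.00429 to 0.112. These 8 include the fits without 2% FBS replicate 3 (0.0517), 10% FBS replicate 1 (0.0658) and 10% FBS replicate 3 (0.0548).

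The G2/M and G1/S lists of cell cycle genes moved in opposite directions. All 25 tested genes of G2/M and mitosis fell, with a median of -0.88 relative to all genes (camera adjusted p = 3.12e-15, and adjusted p = 0.0503 with an estimated correlation). The mitotic kinase gene Aurka fell from 43.9 ± 0.986 to 19.1 ± 0.459 FPKM and Plk1 from 65.3 ± 1.62 to 29.9 ± 1.48 (SD, n = 3). Mki67, the proliferation marker Ki-67, fell from 69.6 ± 0.967 to 44.5 ± 0.907 FPKM (SD, n = 3). Of 27 tested genes of G1/S and DNA replication 19 rose, 2 fell (Rrm1 and Rrm2) and 6 did not pass. Their median was 0.24 relative to all genes (camera adjusted p = 0.0143, and adjusted p = 0.623 with an estimated correlation). Not set against all genes it was 0.36, in a range of 0.18 to 0.40 over the alternatives. Mcm6, a subunit of the replicative helicase, rose from 51.8 ± 0.870 to 86.2 ± 1.90 FPKM and the licensing factor Cdt1 from 31.2 ± 0.246 to 60.0 ± 3.75 (SD, n = 3). Ccnd1, which encodes cyclin D1, had a log2 fold change of 0.01 ± 0.03 (SE, limma adjusted p = 0.71), and a gene on the opposite strand shares 23.4% of its exons. The value for Ccnd1 was -0.13 (adjusted p = 0.00803) with median-of-ratios scaling and 0.11 (adjusted p = 0.00915) with quantile normalization, and its adjusted p ran from 0.00611 to 0.967 over the alternatives. Myc rose from 101 ± 2.69 to 194 ± 3.51 FPKM (SD, n = 3), a log2 fold change of 0.93 ± 0.03 (SE, limma adjusted p = 2.41e-06). Of 30 ribosome biogenesis genes and MYC targets 27 rose and 3 did not pass. Their median was 0.32 relative to all genes (camera adjusted p = 4.14e-05, and adjusted p = 0.418 with an estimated correlation). Nop14 rose from 24.5 ± 0.413 to 70.2 ± 2.22 FPKM and Nop58 from 14.3 ± 0.252 to 27.9 ± 0.981 (SD, n = 3).

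The ATF4 and amino acid response list covers amino acid synthesis and transport under nutrient stress. Of its 24 tested genes 23 rose and 1 did not pass, with a median of 1.33 relative to all genes (camera adjusted p = 4.49e-09, and adjusted p = 0.157 with an estimated correlation). Ddit3, which encodes the stress factor CHOP, rose from 12.1 ± 0.339 to 81.5 ± 3.44 FPKM, and Slc7a11, a cystine transporter, from 1.05 ± 0.0288 to 13.3 ± 0.625 (SD, n = 3). A further list held chaperones of the endoplasmic reticulum (ER) and genes of the unfolded protein response. Of its 21 tested genes 9 rose, 6 fell (7 adjusted over the list alone) and 6 did not pass (camera adjusted p = 0.977). Dnajb9 rose from 24.0 ± 1.32 to 56.5 ± 1.57 FPKM (SD, n = 3). Among p53 targets 9 of 17 rose, 4 fell, Cdkn1a and Mdm2 among them, and 4 did not pass (camera adjusted p = 0.287). Gadd45a, a growth arrest gene, rose from 18.0 ± 1.0 to 133 ± 0.332 FPKM (SD, n = 3). Among quiescence and FOXO targets 12 of 19 rose, 3 fell and 4 did not pass (camera adjusted p = 0.301). Txnip, a thioredoxin inhibitor that limits glucose uptake, rose from 32.6 ± 5.47 to 289 ± 4.61 FPKM (SD, n = 3). In the NRF2 list 14 of 30 rose (15 adjusted over the list alone), 8 fell and 8 did not pass (camera adjusted p = 0.835). In the lysosome and autophagy list 15 of 29 rose and 5 fell (16 and 6 adjusted over the list alone) and 9 did not pass (camera adjusted p = 0.287). Sqstm1, the autophagy receptor p62 and a member of both lists, rose from 171 ± 3.67 to 691 ± 20.3 FPKM (SD, n = 3).

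**Figure D2:**
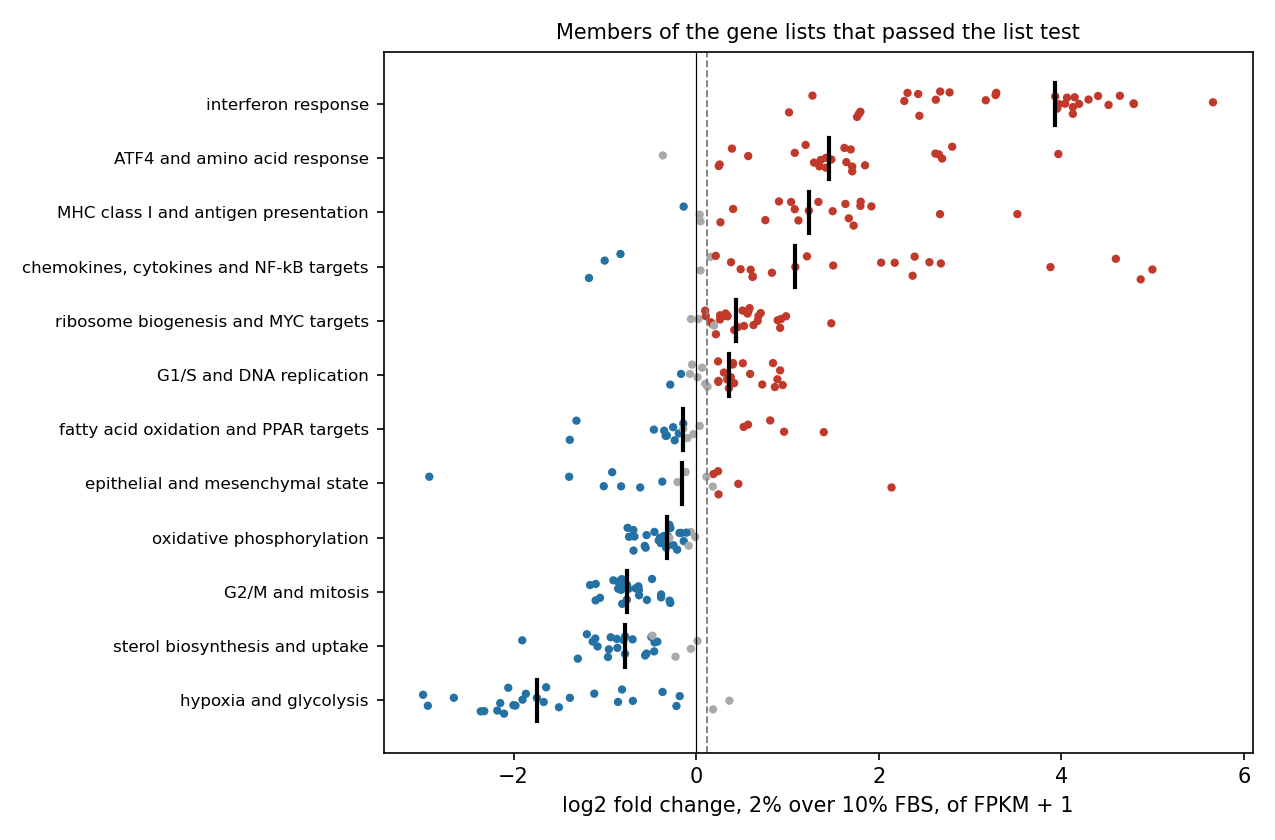
Log2 fold change (2% over 10% FBS, of FPKM + 1) of each tested member of the 12 lists that passed camera with the preset correlation, 6 in each direction. Points are genes, red where higher, blue where lower and grey where not past the threshold, black bars are list medians, and the dashed line is the median of all tested genes, 0.12.

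Genes of cell shape and matrix went both ways. In the matrix list 9 of 19 rose, 9 fell and 1 did not pass (camera adjusted p = 0.403). Mmp13, a collagenase, rose from 2.68 ± 0.206 to 69.0 ± 4.30 FPKM (SD, n = 3), a log2 fold change of 4.25 ± 0.06 (SE, limma adjusted p = 2.05e-07). In the epithelial and mesenchymal list 7 of 16 fell, 5 rose (6 adjusted over the list alone) and 4 did not pass. Its median was -0.28 relative to all genes (camera adjusted p = 0.0451, and adjusted p = 0.166 with an estimated correlation). The members that fell include epithelial genes (Krt8, Krt18 and Tjp1) and mesenchymal genes (Vim, S100a4 and Snai1). Krt8, a keratin, fell from 236 ± 2.97 to 89.6 ± 2.13 FPKM, while Snai2, a repressor of epithelial genes, rose from 9.34 ± 0.474 to 44.5 ± 0.470 (SD, n = 3). The call on the epithelial and mesenchymal list was lost in 10 further alternatives, the replicate block (camera adjusted p = 0.0779), median-of-ratios scaling (0.0862) and quantile normalization (0.0667) among them, in a range of 0.0321 to 0.181. These 10 include the fits without 2% FBS replicate 2 (0.0581) or 3 (0.0667) and without 10% FBS replicate 2 (0.0533) or 3 (0.0509). Of 21 SRF and YAP targets 9 rose, 10 fell (12 adjusted over the list alone) and 2 did not pass (camera adjusted p = 0.301). Axl, a receptor tyrosine kinase, rose from 50.7 ± 0.273 to 105 ± 0.340 FPKM (SD, n = 3), while the actin genes Actb and Actg1 fell. Of 26 immediate early and feedback genes 11 rose, 9 fell and 6 did not pass (camera adjusted p = 0.882). Atf3, a stress-induced transcription factor, rose from 6.04 ± 0.291 to 27.6 ± 1.65 FPKM (SD, n = 3).

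Few markers of other cell types were tested. Of 15 leukocyte markers listed, 4 were tested, of which S100a8, Lyz2 and Cd68 rose and Cd14 fell. S100a8 went from 3.39 ± 0.736 to 21.9 ± 2.80 FPKM (SD, n = 3), while Ptprc, the leukocyte marker CD45, averaged 0.00567 FPKM in 2% FBS. Of 12 endothelial markers listed, 2 were tested, 1 of which did not pass, and Eng rose from 12.6 ± 0.224 to 21.4 ± 0.927 FPKM (SD, n = 3). Of 6 tested fibroblast markers 4 rose, 1 fell and 1 did not pass (camera adjusted p = 0.297), and Pdgfrb rose from 1.57 ± 0.202 to 7.54 ± 0.527 FPKM (SD, n = 3). Of 3 tested markers of alveolar and airway epithelium, Foxa1 and Abca3 rose and Foxa2 fell. Foxa1 rose from 1.91 ± 0.0385 to 2.53 ± 0.0401 FPKM (SD, n = 3, limma adjusted p = 0.0025), a call lost with quantile normalization (adjusted p = 0.625, in a range of 0.00154 to 0.625).

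In the immediate early, fatty acid synthesis, LXR, ER chaperone and matrix lists, which did not pass, the camera direction was lower while the median and mean log2 change, not set against all genes, lay above 0. On the same scale the SRF and YAP list had a median of -0.12 and a mean of 0.04, and the airway list a median of 0.21 and a mean of -0.008.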

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

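The alternatives on fragments estimated from FPKM and on trends with GC content and exon length were chosen after seeing the data. Of the 49 named genes, 46 kept their direction and their side of the threshold under every alternative in which they were tested. Exosc6, Foxa1 and Ccnd1 did not. Of 23 lists tested, 17 kept both under the 15 alternatives for data, scaling, filter and fit, and the interferon, antigen presentation, chemokine, ATF4, ribosome biogenesis, G1/S, hypoxia, G2/M, sterol and oxidative phosphorylation calls are among them, though with an estimated correlation these were lost too. The number of genes higher in 2% FBS was 3463 with the filter at 5 FPKM, where fewer genes are tested. The number at least 2-fold higher was 1059 with a pseudocount of 0.1, which enlarges the log2 change of low genes, 397 with the filter at 5 FPKM, and 1073 with limma-voom, where the cause was not tested. Lists that passed numbered 0 with an estimated correlation, 22 with directional fry and 23 with mixed fry, which do not compare a list with other genes. Ccnd1 was -0.13 with median-of-ratios scaling, -0.14 with trends removed, and -0.002 to 0.034 with 1 library left out.

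Medians here are not set against all genes. That of the fatty acid oxidation list was -0.14 to begin with and, where its call was lost, -0.19 at 5 FPKM, -0.28 with median-of-ratios scaling, -0.28 with quantile normalization, -0.14 with limma-voom and -0.30 with trends removed, and it was -0.17 to -0.13 with 1 library left out. That of the epithelial and mesenchymal list was -0.16 to begin with, 0.014 without a filter, -0.29 at 5 FPKM, -0.30 with median-of-ratios scaling, -0.17 with quantile normalization, -0.16 with the replicate block, -0.27 with trends removed, and -0.26 (without 2% FBS replicate 1) to -0.063 (without 10% FBS replicate 2) with 1 library left out. The lysosome list passed with quantile normalization (median 0.27, adjusted p = 0.0397, in a range of 0.0397 to 0.455). The camera direction of 3 lists that did not pass turned. The ER chaperone list had a median of 0.13 without a filter, 0.12 at 5 FPKM, 0.12 with quantile normalization (where it passed, adjusted p = 0.0259, in a range of 0.0259 to 0.986), 0.17 without the 20 most abundant genes, 0.14 with limma-voom, and 0.09 to 0.16 with 1 library left out. The immediate early list had 0.072 without a filter, 0.01 with quantile normalization and -0.022 with trends removed, and the LXR list 0.17 without a filter and 0.033 with trends removed. For Ccnd1 and these lists the cause was not tested.

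Leaving out each library in turn, on the same genes, gave 4904 to 5049 higher, 2556 to 2653 lower, 601 to 624 at least 2-fold higher, 262 to 280 at least 2-fold lower, and 10 to 12 lists. Leaving out a library was first tried with the filter applied anew to the other 5. Without a 2% FBS library that gave 424 to 434 genes at least 2-fold higher and left 11 interferon genes tested (median 2.26 to 2.35), since genes near 0 in 10% FBS then have too few libraries to be kept. With the replicate block 5033 genes were higher and 2637 lower. The numbers did not pair the libraries, since deviations of same-numbered libraries correlated at -0.076, -0.021 and -0.038. Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave as many genes or lists. The real counts were 5319 higher, 2807 lower, 608 and 265 at least 2-fold changed, and 12 lists, and the highest of the other splits were 1, 1, 1 and 1 genes and 10 lists. With 10 splits a share under 0.05 cannot be reached. Every other split also mixes the serum groups, which puts the difference between them into the spread within each side. Low gene counts were bound to follow, so the gene counts of those splits cannot decide the question. Alternatives for counts (edgeR and DESeq2 tests and scaling, voom on counts, count filters) were not run, since the values are FPKM, nor was edgeR on recovered reads, since whole reads were not recovered. The read counts are unknown, so no detection limit is given for genes listed at 0.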

Other observations

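The gene families and single genes of the first paragraphs were picked after their values were seen, and the tests on leukocytes, near-identical copies, library depth, background reads and the trends with GC content and length were also chosen after the result was seen, as was the bound of the scaling test, whose scalings had been fixed before. The test on early-embryo genes was chosen after related genes had been seen to switch on in these libraries, though before the values of its own families were. Of 20 cytosolic aminoacyl-tRNA synthetase genes, which charge transfer RNAs with amino acids, 16 rose in 2% FBS and 4 (Hars, Dars, Kars and Qars) fell. Their median log2 change was 0.85, and 0.71 to 0.89 over the scalings (camera adjusted p = 0.002 over the families, and adjusted p = 0.219 with an estimated correlation). Their summed expression went from 773 ± 16.4 to 1235 ± 14.8 FPKM (SD, n = 3). A larger set of 44 aminoacyl-tRNA biosynthesis genes, from the pathways tested below, did not pass (25 rose, 7 fell, camera adjusted p = 0.202). Of 12 tested genes of glycogen metabolism 8 fell and 2 rose (median -0.23, and -0.40 to -0.20 over the scalings, camera adjusted p = 0.00152, and adjusted p = 0.208 with an estimated correlation). Pgm2, a phosphoglucomutase gene, fell from 83.7 ± 5.49 to 14.4 ± 0.272 FPKM and the branching enzyme gene Gbe1 from 36.3 ± 1.52 to 7.56 ± 0.295 (SD, n = 3). Of the 13 messages of the mitochondrial genome 11 fell (median -0.48, and -0.63 to -0.31 over the scalings, camera adjusted p = 3.46e-06, and adjusted p = 0.208 with an estimated correlation). Among them mt-Nd1 fell from 2271 ± 52.5 to 1083 ± 48.4 FPKM, while mt-Co1 stood at 7224 ± 261 in 10% FBS and 7404 ± 262 in 2% FBS (SD, n = 3). Of 14 genes of the 20S proteasome core 13 fell (median -0.26, and -0.40 to -0.19 over the scalings, camera adjusted p = 1.62e-05, and adjusted p = 0.208 with an estimated correlation), while the immunoproteasome genes Psmb8, Psmb9 and Psmb10 rose. Of 79 tested cytosolic ribosomal protein genes 32 fell and 4 rose (median -0.12, and -0.27 to 0.08 over the scalings, camera adjusted p = 3.46e-06, and adjusted p = 0.219 with an estimated correlation). Histone cluster genes summed to 1455 ± 171 FPKM in 10% FBS and 493 ± 102 in 2% FBS (SD, n = 3), with 12 of 24 tested lower and 3 higher (median -0.27, and -0.40 to -0.24 over the scalings, camera adjusted p = 0.00152, and adjusted p = 0.208 with an estimated correlation). Most of that sum came from Hist1h2ap (658 and 188 FPKM) and Hist1h2ao (510 and 146 FPKM). Apart from Hist1h1c and Hist1h2bc the genes that fell encode histone H2A, and no tested H3 or H4 gene fell. The 3 that rose were Hist1h4h, Hist2h2be and Hist3h2a. Near-identical copies of histone genes were not searched for. Most histone messages lack a poly(A) tail, and how RNA was selected is not given in the sources used here.

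Soat2, which esterifies cholesterol, rose from 1.44 ± 0.129 to 30.6 ± 2.03 FPKM and Abcg1, which exports it, from 1.23 ± 0.271 to 9.49 ± 1.01 (SD, n = 3). Gdf15, a stress-induced hormone, rose from 3.81 ± 0.250 to 51.0 ± 1.26 FPKM (SD, n = 3). Aars rose from 22.7 ± 0.720 to 51.1 ± 1.37 FPKM (SD, n = 3), in contrast to Exosc6, whose exons lie within it. Of 269 pathways given in the files, 43 passed camera, 35 lower and 8 higher, and 0 did so with an estimated correlation. The lowest adjusted p overall were falls, in Parkinson's disease (camera adjusted p = 2.21e-09, and adjusted p = 0.241 with an estimated correlation) and oxidative phosphorylation (camera adjusted p = 5.94e-09, and adjusted p = 0.241 with an estimated correlation). The lowest adjusted p among those that rose was shared by allograft rejection and autoimmune thyroid disease, which hold MHC genes, with 14 of 15 genes higher in each (camera adjusted p = 0.000212, and adjusted p = 0.31 with an estimated correlation). DNA replication did not pass, with 22 of 35 genes higher and 5 lower (camera adjusted p = 0.272). Nor did cell cycle, with 43 of 115 genes higher and 35 lower (camera adjusted p = 0.372). The 15 type I and III interferon genes listed summed to 0.541 ± 0.0357 FPKM in 2% FBS and 0.407 ± 0.182 in 10% FBS (SD, n = 3), and none reached the filter. A further family held sensors of cytosolic nucleic acid together with adaptors, signalling proteins and enzymes of that pathway, such as Mavs, Tbk1, Irf3 and Trex1. Of its 11 tested genes 8 rose and 2 fell (median 0.49, and 0.36 to 0.54 over the scalings), but the family did not pass (camera adjusted p = 0.0887, and adjusted p = 0.208 with an estimated correlation). The sensors Ddx58, Ifih1 and Dhx58, which rose, were counted in the interferon list and not in this family.

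The rise of interferon response genes is the first pattern weighed. Leukocytes are argued against by their markers, whose highest median in a 2% FBS library was 0.0506 FPKM over 15 genes. The list mixes several leukocyte types, so its median alone cannot speak for a single type. Cd68, Cd14 and S100a8 averaged 23.4, 12.2 and 21.9 FPKM in 2% FBS, and 15.2, 14.9 and 3.39 in 10% FBS. Lyz2, Fcer1g and Csf1r averaged 1.32, 0.216 and 0.0292 in 2% FBS, and 0.155, 0.0536 and 0.0038 in 10% FBS. But Ptprc, Laptm5 and Coro1a averaged 0.00567, 0.0159 and 0.147 in 2% FBS, and 0.00391, 0.0338 and 0.107 in 10% FBS. Reads shared between near-identical copies are argued against by the 27 members without such a copy, which all rose, with a median log2 change of 3.28. Of 24 genes picked by symbol as early-embryo genes linked to endogenous retroviruses, only Usp17la and Usp17ld were tested, and both rose. Whether each of these 24 genes has such a link in Lewis cells was not tested. All genes of the Zscan4, Tcstv, Usp17l, Tdpoz, Zfp352 and Dux families summed to 15.6 ± 0.745 FPKM in 2% FBS and 0.413 ± 0.151 in 10% FBS (SD, n = 3), a ratio of 37.8. Usp17l genes made up 12.4 and 0.347 FPKM of these sums. The other 19 genes, none of which reached the filter, summed to 3.22 ± 0.443 and 0.0658 ± 0.0578 FPKM (SD, n = 3). As a hypothesis, retroviral transcripts may be one trigger of interferon sensing in low serum, which reads over repeats would test, but they were not analysed here, the idea came from the same libraries, many of these genes are low and near-identical, and the order of events and other effects of serum stay open.

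The second pattern is that 24162 ± 218 genes were listed above 0 in 2% FBS and 22150 ± 144 in 10% FBS (SD, n = 3), with 592 genes at 0 in every 10% FBS library and above 0 in every 2% FBS library against 81 the other way. Deeper 2% FBS libraries are argued against by a ratio of estimated fragments of 0.955 (2% over 10% FBS), if the step of each library is 1 fragment. Over chemoreceptor genes, silent in most tissues, the mean FPKM weighted by exon length had a ratio of 2.70 (2% over 10% FBS), and this rise spread evenly over all exons, as by reads from genomic DNA, would give 181% of the observed gain in genes above 0. Background stays open, since that is more than enough, yet the chemoreceptor genes above 0 grew by 72 where an even spread would give 224. The value of 181% met the bound first set for background as the cause. The condition on the number of chemoreceptor genes above 0 was added after that value was seen. Broader transcription of silent genes in low serum is a hypothesis that was not tested here, and reads over introns and between genes would test it against background.

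The third pattern is the fall of hypoxia and glycolysis genes. Scaling between libraries is argued against by a highest median log2 change of -1.64 over the scalings tried, shared reads by a median of -1.69 over the 24 members without a near-identical copy, and GC content or exon length by a median of -1.86 once those trends were removed. Cell density and oxygen at harvest, which could differ between cultures in 10% and 2% FBS, were not tested and stay open beside serum itself, so a response to low serum is a hypothesis, which cultures matched for density and oxygen would test.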
